A study of Homo sapiens with 23 samples.

How the data were processed

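RNA sequencing was analysed from 23 libraries of the prostate cancer cell lines LNCaP and LAPC4, in 9 groups, grouped as the sample labels name them. Per the labels, total RNA was extracted on silica columns, LNCaP was grown in RPMI with serum, and LAPC4 in IMDM with serum and R1881. Per the submitters' processing notes, reads were checked with FastQC 0.9.0 and aligned with Bowtie2 to hg38. The counter, the annotation release and any filter are not given in the sources used here.

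The values came as 3 tables. For LAPC4, the authors deposited whole-number read counts per Ensembl gene. For the LNCaP overexpression and knockdown groups, the authors deposited estimated counts per Ensembl gene, which need not be whole and were rounded to whole numbers here. The third table holds the drug experiment by gene symbol. Its vehicle and combination columns are estimated counts as deposited, rounded here in the same way, while its enzalutamide columns are whole counts as deposited. The enzalutamide columns therefore came from another counting step than the 6 columns they were compared with. They also carry no replicate number that ties a column to a sample, so they were used as members of their group only. Symbols that stood on several lines of the drug table were summed. A current symbol was found for 99.5% of the identifiers in the LNCaP table, 98.7% in the LAPC4 table and 64.7% in the drug table, and unmatched identifiers kept the name they had. Library totals ran from 20964025 to 23272088 counts in the LNCaP table, from 28586064 to 30465978 in the LAPC4 table and from 22615580 to 28241076 in the drug table. Coordinates, gene overlaps and copies are from GENCODE 29 on hg38. A second annotated copy here means a pseudoautosomal gene, annotated on both X and Y. Other duplicated genes were not marked.

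Choices of samples, tests, gene lists, naming rule and alternatives were fixed before the data were examined, except where the text says otherwise. Each comparison was tested with edgeR 4.0.16 in R 4.3.3. The steps were TMM scaling, filtering with filterByExpr, a quasi-likelihood F-test (glmQLFit and glmQLFTest) and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. The LNCaP overexpression, LNCaP knockdown and LAPC4 comparisons were fitted on their own groups alone. The 3 drug arms were fitted together, so they share an estimate of the spread. Standard errors of log2 fold changes were derived from the F statistic. Levels are CPM on the TMM-scaled library size of the fit, with the SD over libraries. The difference between lines was an interaction contrast in a joint model over genes with the same identifier in both tables, which compares ratios formed within each table.

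For a gene at 0 in every library of a group, the fold is a lower bound, computed from the mean CPM of the other group and a floor of 3 counts per library. Where a group held 1 to 3 counts in all, the ratio is given with an exact 95% binomial (Clopper-Pearson) interval. Bounds and intervals cover counting error only, since the reads carry no molecular identifiers.

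The 25 fixed gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists within a comparison, and again with an estimated correlation and with fry. Results are reported for 23 of them, and the other 2 lists and some genes are not reported here. The 23 lists were androgen glucuronidation, steroid synthesis and conversion, neuroendocrine markers, glucocorticoid receptor and targets, luminal prostate epithelium, basal and stem markers, mesenchymal genes, cell cycle, hypoxia and glycolysis, sterol synthesis, fatty acid synthesis, amino acid and ATF4 response, endoplasmic reticulum chaperones, interferon-stimulated genes, p53 targets, Wnt pathway, hepatic and intestinal lineage, receptor kinases and ligands, splicing and chromatin regulators, stromal, endothelial and blood cell markers, mitochondrially encoded genes, replication-dependent histones and cytosolic ribosomal proteins. Only lists with at least 3 tested members entered.

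Named genes followed a fixed rule. ONECUT2 came first, then NR3C1, FOXA1, HOXB13, REST, SRRM4, UGT2B15 and UGT2B17. Next were the 10 steepest rises and 10 steepest falls with an adjusted p past the threshold, a mean of at least 5 CPM in the higher group, no overlap between the libraries of the groups and an approved symbol. From each list, up to 4 called members with the largest change and up to 2 uncalled members with the highest level could be named.

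The procedure was tested on simulated counts with the library sizes and gene means of each comparison, in which 200 genes were changed. For LNCaP overexpression, 76% of 2-fold and 100% of 4-fold changes were recovered, and 22 unchanged genes of the 17046 were called. For LAPC4 overexpression these figures were 90% and 100%, with 12 unchanged genes called of 16904. For the knockdown they were 88% and 100%, with 18 of 16585. For combination vs vehicle they were 76% and 100%, with 9 of 17439. For enzalutamide vs vehicle they were 70% and 100%, with 20 unchanged genes called, and for combination vs enzalutamide 74% and 100%, with 11. In each of these simulations the unchanged genes made up more than 0.05 of all calls. Recovery of 1.5-fold changes lay between 46% and 84%. Far more genes were called in the data than the 200 changed here, so these figures may not carry over.

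Replicates within a group were compared by a chi-square of their counts. The statistic per degree of freedom lay between 3.35 and 77.1, so no library was taken for a repeat of another. The highest values, 77.1 and 51.7, set the first enzalutamide column against the other enzalutamide columns, which had 22.4 between them. The labels do not say that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical.

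The alternatives were DESeq2 size factors, library totals without further scaling, DESeq2 1.42.0 and limma-voom as tools, no filter on low counts, a filter at a mean of 5 CPM, a minimum absolute log2 fold change of 1, a replicate block, leaving out each library in turn and fitting only the arms compared. Chosen after seeing the data were a fit of all 4 LNCaP groups, the shCon libraries as reference for LNCaP overexpression, a replicate block on the vehicle and combination libraries, and a restriction of the drug comparisons to genes without exonic overlap that were counted in every arm. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.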

Results

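The series follows ONECUT2 (OC2), a CUT-homeodomain transcription factor, in prostate cancer cells. Its gene lies on chromosome 18 from 57435685 to 57491297 on the plus strand (hg38) and shares no exon with another gene. OC2 was overexpressed in LNCaP (2 libraries beside 2 control libraries) and in LAPC4 (3 beside 3 vector libraries). It was targeted with a short hairpin in LNCaP (2 shOC2 libraries beside 2 shCon libraries). In a drug experiment, LNCaP cells were treated for 7 days with vehicle, with enzalutamide at 10 µM, or with enzalutamide at 10 µM plus an OC2 inhibitor at 10 µM (3 libraries each). The 23 libraries held between 20964025 and 30465978 counts.

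**Figure D1:**
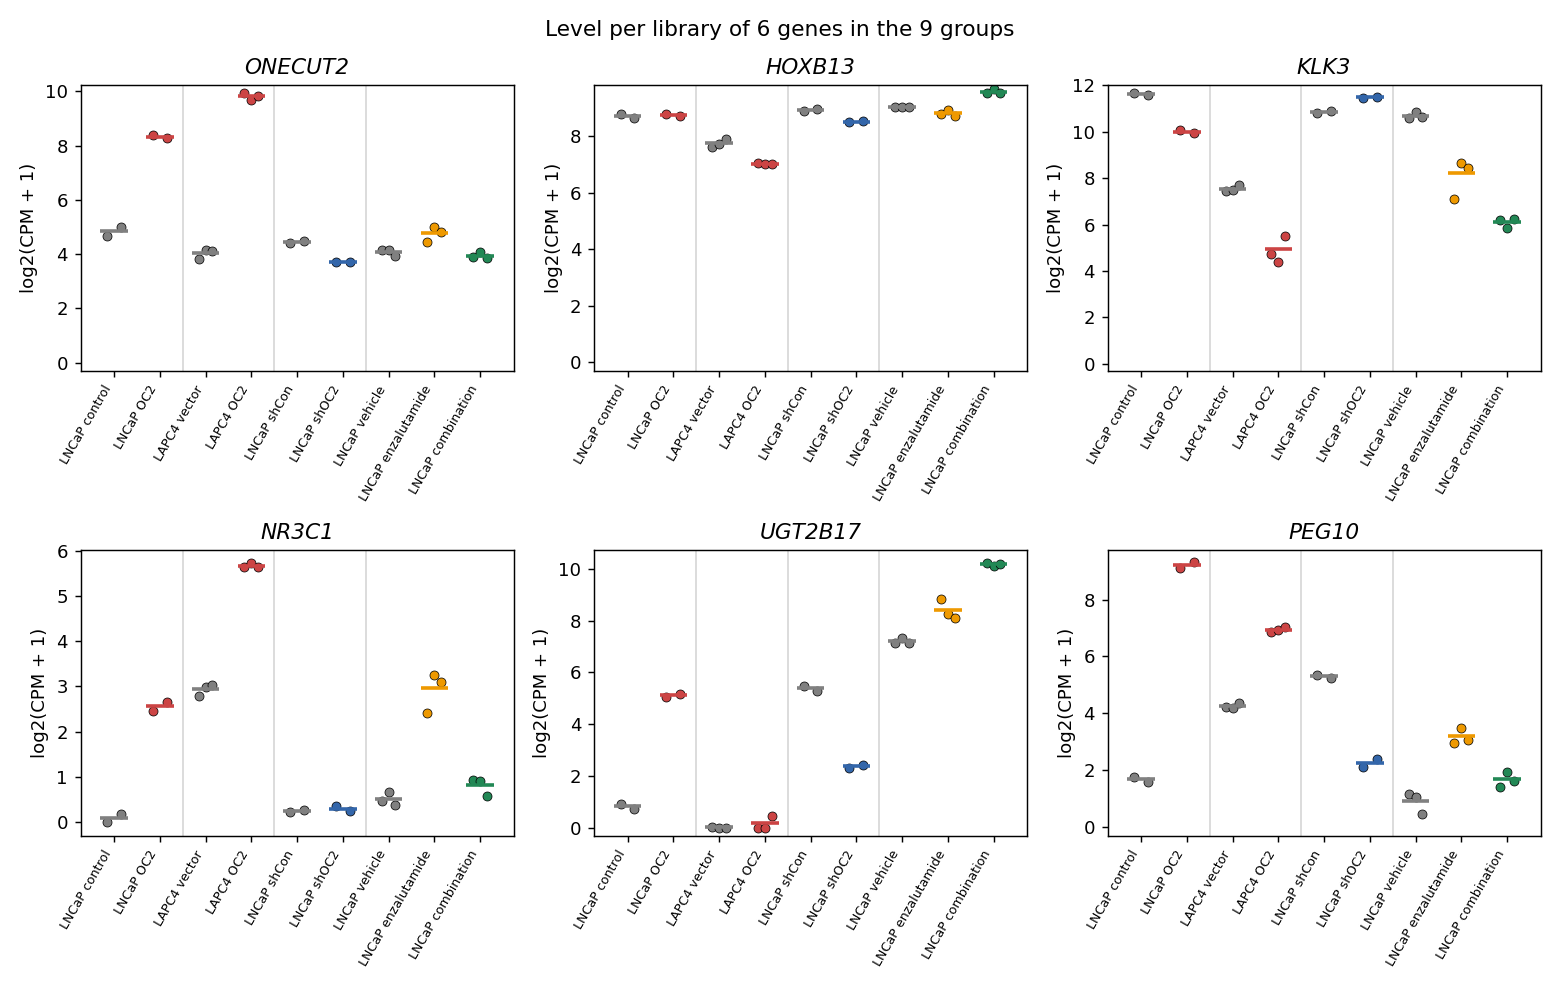
Level of 6 genes in each library of the 9 groups (horizontal axis), as log2(CPM + 1) (vertical axis), with bars at the log of group means. CPM were TMM-scaled over all libraries and genes of a table, so they differ slightly from the levels in the text. ONECUT2 lies above its controls in every overexpression library of both lines and below shCon in both shOC2 libraries.

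The first comparison asked what a higher level of OC2 changes in LNCaP. ONECUT2 stood at 301 ± 19.0 CPM (SD, n = 2) in overexpressing cells and 26.4 ± 4.14 CPM (n = 2) in control, 11.4-fold higher (log2 fold change 3.51, SE 0.11, edgeR adjusted p = 9.78e-09). NR3C1, the glucocorticoid receptor, reached 4.62 ± 0.50 CPM against 3 counts in all in control, a ratio of 69.5 (95% interval 23.4 to 339.6). SRRM4, a neural splicing factor, stood at 108 ± 6.89 CPM and at 0 in both control libraries, at least 776-fold higher on a floor of 3 counts per library. FOXA1 rose 1.18-fold (adjusted p = 0.0197), a call that ended without control replicate 2 (log2 fold change 0.17, adjusted p = 0.0985), without overexpression replicate 1 (0.18, 0.233) or without overexpression replicate 2 (0.29, 0.0579). HOXB13 (log2 fold change -0.01, SE 0.07) and REST (-0.09, SE 0.08) did not pass the test.

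Of 15 tested neuroendocrine markers, 14 rose and 1 fell (camera adjusted p = 9.13e-19, adjusted p = 0.129 with an estimated correlation). Other members of the list did not pass the filter. Of the 15, 3 were at 0 in control and could enter only as rises, so the count leans to rises. Here and below, counts adjusted over the list alone are given only where they differ. SCG3, a secretory granule protein, stood at 23.5 ± 2.08 CPM against 1 count in all in control, and the granule protein CHGB and the synaptic vesicle protein SV2A were at least 82.9-fold and 92.3-fold higher. All 6 tested androgen glucuronidation genes rose (adjusted p = 3.04e-30, adjusted p = 0.129 with an estimated correlation), among them UGT2B11 at 314 ± 10.5 CPM against 1.49 ± 0.54 and UGT2B28 at 71.9 ± 1.11 against 0.27 ± 0.02. UGT2B15 rose 38.6-fold and UGT2B17 43.3-fold, but the pair is near-identical in sequence, so the split of reads between them is uncertain. PEG10, a retrotransposon-derived gene, was 269-fold higher at 563 ± 50.3 CPM.

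KLK3, which encodes prostate-specific antigen, fell 3.11-fold (log2 fold change -1.64, SE 0.07) to 972 CPM, and the cation channel gene TRPM8 fell from 49.3 ± 1.02 to 4.11 ± 0.22 CPM. HPGD, which encodes a prostaglandin-degrading enzyme, rose 27.5-fold. FKBP5 (log2 fold change -0.13, SE 0.07) did not pass the test. Mesenchymal genes rose in 7 of 12 cases and fell in 1 (camera adjusted p = 2.56e-05, adjusted p = 0.203 with an estimated correlation). TWIST1 reached 39.3 ± 0.12 CPM from 0.13 ± 0.01, and CDH2, which encodes N-cadherin, 4.62 ± 0.56 CPM from 1 count in all.

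The amino acid and ATF4 response rose in 13 of 20 genes and fell in 3 (camera adjusted p = 0.00146, adjusted p = 0.365 with an estimated correlation), with the amino acid transporter subunit SLC3A2 5.39-fold higher. Splicing and chromatin regulators rose in 11 of 20 and fell in 2 (12 and 2 adjusted over the list alone, adjusted p = 0.0125, adjusted p = 0.621 with an estimated correlation), with SRRM3, a relative of SRRM4, 4.43-fold higher. Endoplasmic reticulum chaperones fell in 11 of 18 and rose in 0 (12 and 0 adjusted over the list alone, adjusted p = 0.0470, adjusted p = 0.696 with an estimated correlation). Replication-dependent histones fell in 14 of 15 (adjusted p = 1.33e-12, adjusted p = 0.141 with an estimated correlation), H3C10 by 7.40-fold, and cytosolic ribosomal proteins rose in 27 of 35 (adjusted p = 0.00146, adjusted p = 0.623 with an estimated correlation). Luminal prostate epithelium genes went 6 higher and 6 lower of 18 (adjusted p = 0.144). Among the higher ones, AGR2, a secreted disulfide isomerase, stood at 513 ± 6.02 CPM against 0.95 ± 0.16, and the transcription factor gene GATA3 at 36.6 ± 0.92 against 0.09 ± 0.07.

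The steepest rises included MAGEA4, a cancer-testis antigen gene at 64.9 ± 1.89 CPM (at least 468-fold), SLFN11, a replication stress gene (at least 154-fold), and C1QL4, at 942 ± 17.5 CPM against 0.15 ± 0.02. The steepest falls included the trypsinogen gene PRSS1 (at least 79.4-fold), FBLN2, which encodes the matrix protein fibulin-2 (at least 51.3-fold), and DPP4, a membrane peptidase gene that fell from 124 ± 8.28 to 0.38 ± 0.09 CPM. The shCon libraries also held little of DPP4 (9 counts each) and PRSS1 (16 and 8 counts), so these 2 falls stand only against control. In all, 10366 of 17046 tested genes changed, 5380 higher and 4986 lower, and 4233 of them by at least 2-fold. The control sets of the LNCaP table differed from each other: 9466 of 16790 genes were called between shCon and control. Against shCon, a reference chosen after seeing the data, 5853 of 10007 genes called against control and tested in both kept their direction and their call, and 1362 were called the opposite way. The neuroendocrine list was higher in 14 of 15 against shCon and glucuronidation in 5 of 7, but UGT2B17 was lower (log2 fold change -0.28, SE 0.08), as was FOXA1 (-0.20, SE 0.06), histones were split (4 higher and 4 lower of 12) and chaperones were higher in 15 of 18. Mesenchymal genes went 6 higher and 4 lower of 12 against shCon. Log2 fold changes against shCon were 1.54 for UGT2B15, 0.91 for HPGD, 1.89 for TWIST1, 3.94 for PEG10, -0.84 for KLK3 and -0.80 for H3C10, and the uncalled genes HOXB13 (-0.20), REST (-0.18) and FKBP5 (0.58) were called. The rises also shrank for UGT2B28 (8.05 to 4.66), UGT2B11 (7.70 to 5.97), AGR2 (9.06 to 6.48) and C1QL4 (12.52 to 9.24). Others grew, among them SRRM3 (2.15 to 4.30) and GATA3 (8.60 to 9.68).

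The second comparison put the same question to LAPC4. ONECUT2 stood at 895 ± 82.7 CPM (SD, n = 3) against 15.5 ± 1.97 in vector (n = 3), 57.7-fold higher (log2 fold change 5.85, SE 0.12, edgeR adjusted p = 2.85e-10). FOXA1 fell 2.03-fold and HOXB13 fell 1.67-fold, while NR3C1 rose 7.47-fold from 6.68 ± 0.61 CPM. REST (log2 fold change -0.05, SE 0.08) and UGT2B15 (-0.18, SE 0.15) did not pass the test, and SRRM4 had 0 counts in all 6 libraries.

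Mesenchymal genes rose in 11 of 18 cases and fell in 2 (camera adjusted p = 1.28e-11), the only list in this comparison whose call held with an estimated correlation (adjusted p = 0.0361 with an estimated correlation). VIM, which encodes vimentin, rose from 1.44 ± 0.47 to 829 ± 67.7 CPM, and ZEB1 rose 101-fold. Stromal, endothelial and blood cell markers were higher in 4 of 8 and lower in 0 but did not pass the test (adjusted p = 0.262), among them the collagen gene COL1A2 at 8.75 ± 1.65 CPM against 0.05 ± 0.04. Basal and stem markers rose in 8 of 12 and fell in 1 (adjusted p = 0.000128, adjusted p = 0.116 with an estimated correlation), with the hyaluronan receptor gene CD44 447-fold, KRT14 11.5-fold and KRT5 4.92-fold higher. Luminal prostate epithelium genes fell in 13 of 18 and rose in 3 (4 adjusted over the list alone, adjusted p = 0.00140, adjusted p = 0.116 with an estimated correlation), while KRT19 rose 2.22-fold. KLK2 fell 6.16-fold and KLK3 6.21-fold, and the mesenchymal transcription factor gene SNAI2 rose 23.2-fold.

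Neuroendocrine markers rose in 8 of 11 and fell in 2 (camera adjusted p = 0.00692, adjusted p = 0.132 with an estimated correlation). SV2A rose 67.8-fold and SYT1, a synaptic vesicle calcium sensor gene, 48.2-fold. Glucocorticoid receptor and targets rose in 11 of 20 and fell in 7 (adjusted p = 0.00508, adjusted p = 0.238 with an estimated correlation), with MT2A 13.7-fold and BIRC3 15.2-fold higher. Interferon-stimulated genes rose in 15 of 20 and fell in 3 (adjusted p = 0.000128, adjusted p = 0.132 with an estimated correlation), led by PSMB8 at 61.9-fold and IFI6 at 45.8-fold. The p53 targets rose in 8 of 18 and fell in 2 (adjusted p = 0.0185, adjusted p = 0.144 with an estimated correlation), with CDKN1A (log2 fold change 3.59, SE 0.17) and TP53I3 (3.54, SE 0.12) higher.

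Splicing and chromatin regulators fell in 9 of 18 and rose in 3 (camera adjusted p = 0.0397, adjusted p = 0.333 with an estimated correlation), among them the epithelial splicing factor gene ESRP2, 2.37-fold lower. All 13 mitochondrially encoded genes fell (adjusted p = 1.20e-08, adjusted p = 0.132 with an estimated correlation), MT-ND4 from 15222 ± 1119 to 5040 ± 503 CPM, and replication-dependent histones rose in 13 of 15 (adjusted p = 0.00140, adjusted p = 0.116 with an estimated correlation), H2BC5 5.47-fold. Receptor kinases and ligands rose in 8 of 20 and fell in 12; their median log2 fold change was -0.43 and their mean 1.81 (1.58 with NRG1 at its bound), and camera gave a higher direction (adjusted p = 0.00825, adjusted p = 0.132 with an estimated correlation). AXL, EREG and MET rose to 229 ± 7.29, 45.4 ± 3.12 and 95.3 ± 4.77 CPM from under 1 CPM, and NRG1 was at least 203-fold higher.

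The steepest rises included genes at 0 in all vector libraries, such as BNC1, a keratinocyte transcription factor gene (at least 225-fold), and HEXA, a lysosomal hexosaminidase gene (at least 246-fold). HEXA shares exons with another gene and stood at 55.3 CPM in LNCaP control, so a loss in counting is not ruled out for its 0 in LAPC4 vector, although the overexpression libraries of the same table counted it. The steepest falls were smaller, PLCH2 at 30.6-fold and ENPP3 at 13.4-fold. In all, 10329 of 16904 tested genes changed, 5427 higher and 4902 lower, and 3548 by at least 2-fold. Genes with at least 5 CPM in the higher group rose at least 16-fold in 345 cases and fell as far in 1. EEF1G, TOMM6 and all 18 protein-coding pseudoautosomal genes, which have a second annotated copy in the reference, had 0 counts in every LAPC4 library. This table therefore cannot speak for these genes.

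**Figure D2:**
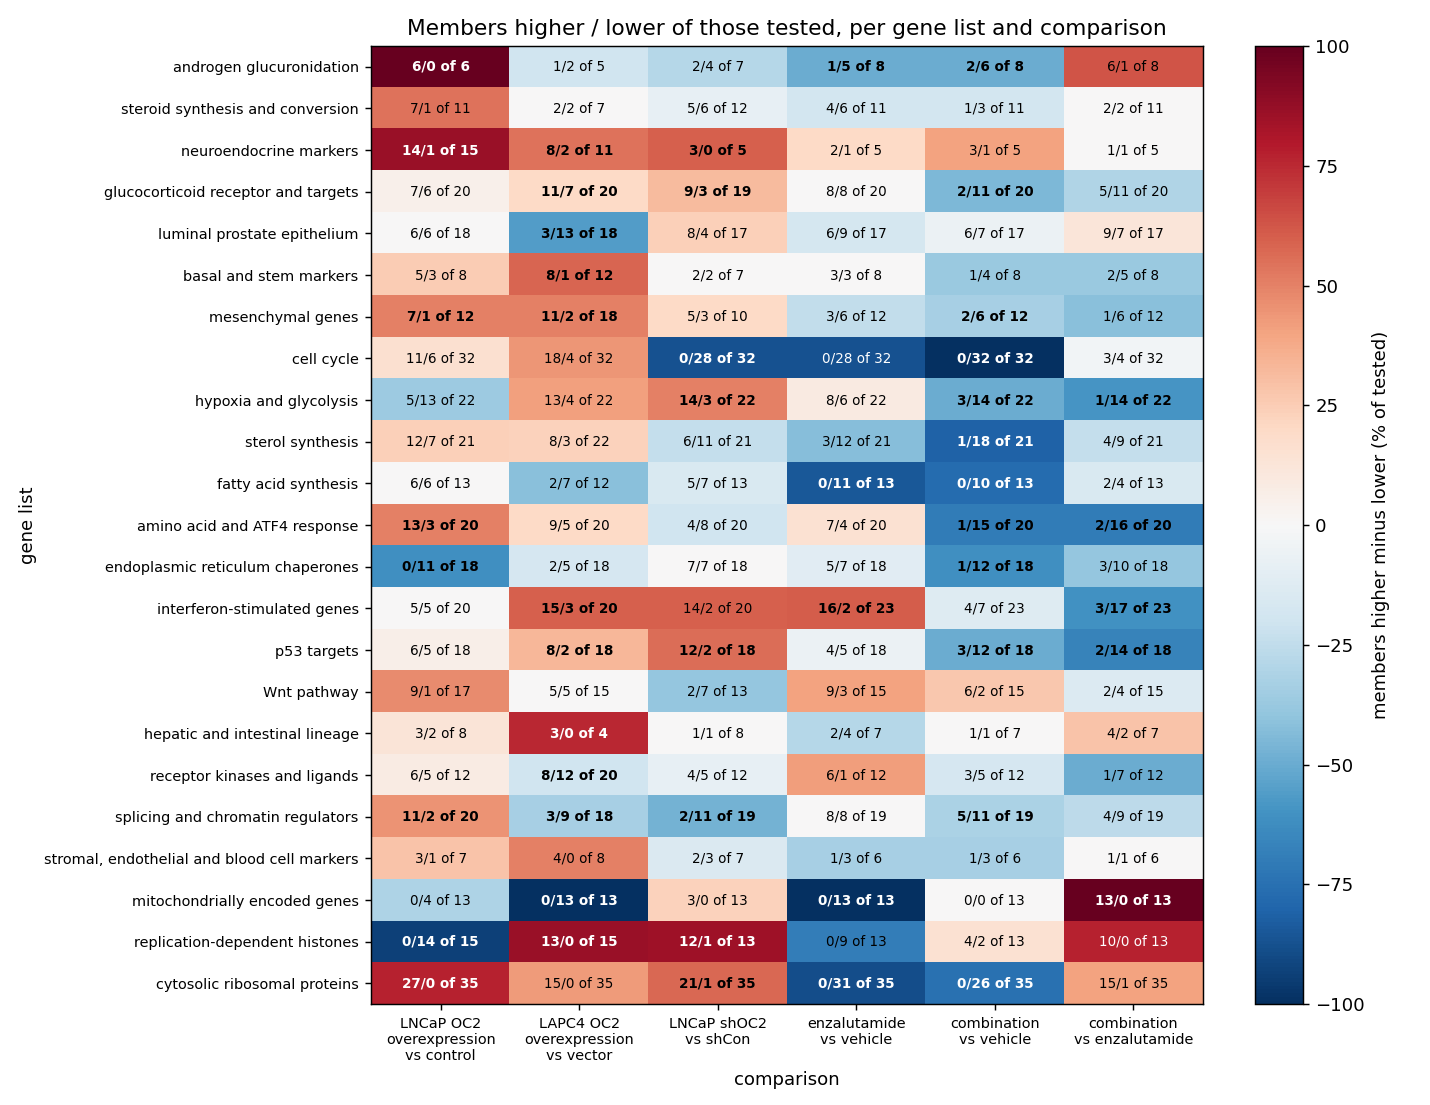
Members higher and lower of those tested for 23 gene lists (vertical axis) in 6 comparisons (horizontal axis), with colour for members higher minus lower as a percentage of tested, and bold for lists called by camera at the preset correlation. Neuroendocrine markers are higher in 14 of 15 and 8 of 11 members with overexpression.

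Between the lines, the effect of overexpression differed for 9713 of 19633 genes in the joint model, 4979 with a larger log2 fold change in LAPC4 and 4734 with a smaller (edgeR interaction test). The tables were counted differently, so the test rests on ratios formed within each table. ONECUT2 itself rose further in LAPC4 (difference of log2 fold changes 2.34, SE 0.17). A different response of the lines therefore cannot be told apart from a different rise in OC2. FOXA1 (difference of log2 fold changes -1.26, SE 0.11) and HOXB13 (-0.73, SE 0.11) responded lower in LAPC4, as did NR3C1 (-3.12, SE 0.55) and UGT2B15 (-5.45, SE 0.20). Line cannot be told apart from medium in these differences, since the labels name other media for the lines and R1881 for LAPC4 only. The differences also depend on the LNCaP control libraries, which held 3 counts of NR3C1 in all. Against shCon, the log2 fold change in LNCaP was 4.66 for NR3C1, 1.54 for UGT2B15 and -0.20 for FOXA1, in place of 6.01, 5.27 and 0.24. Of the 14601 genes tested in both lines, 1715 rose in both, where independent lists of these sizes would share 1512, and 1351 fell in both against 1215. Another 2534 were called in opposite directions, no more than independent lists would share. Of these, 1354 rose in LNCaP and fell in LAPC4, against 1375, and 1180 went the other way, against 1336. Across genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.17 and a Spearman correlation of 0.08.

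**Figure D3:**
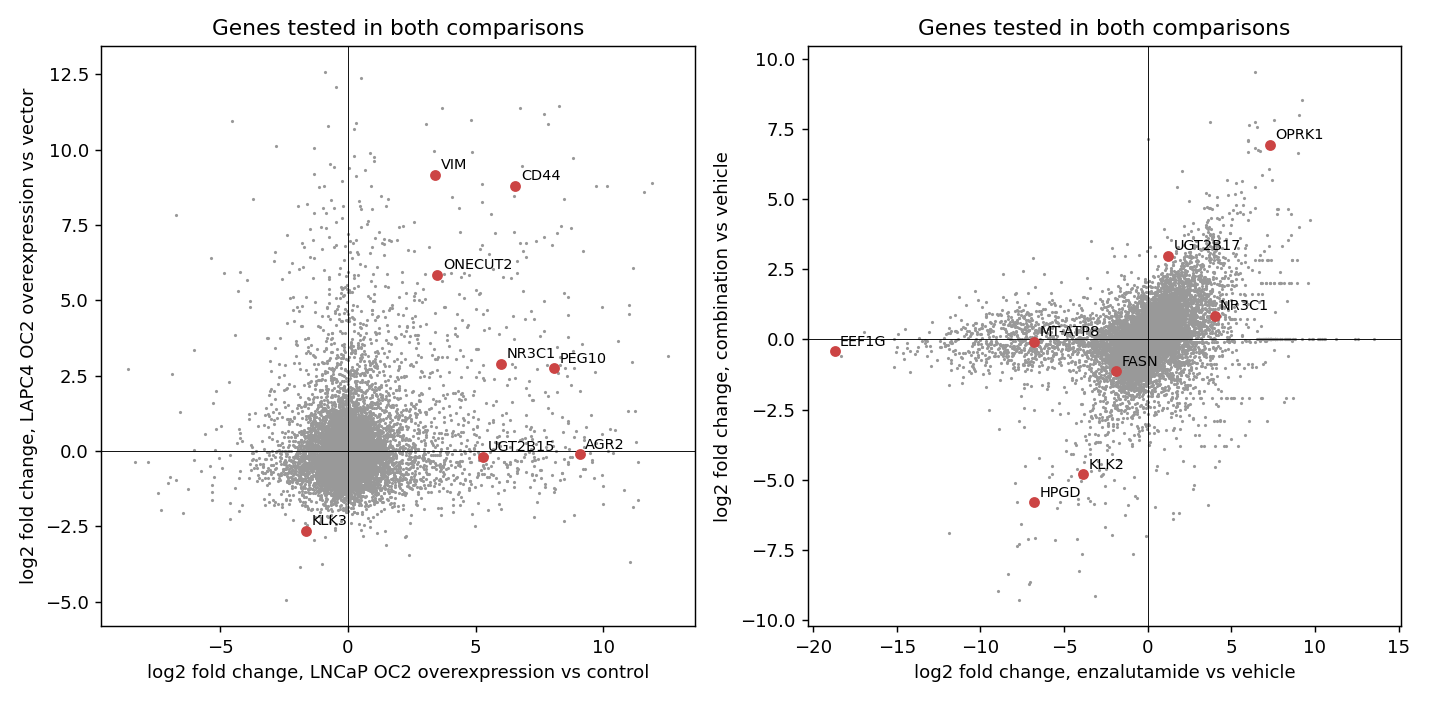
Log2 fold changes per gene, for LNCaP (horizontal) against LAPC4 overexpression (vertical) on the left and enzalutamide vs vehicle (horizontal) against combination vs vehicle (vertical) on the right, with named genes in red. The Pearson correlation on the left is 0.17, and values of genes at 0 in a group, such as EEF1G under enzalutamide, are fitted and no bound.

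The third comparison asked the reverse question with a hairpin against OC2 in LNCaP. ONECUT2 fell 1.71-fold, from 21.8 ± 0.48 CPM in shCon to 12.8 ± 0.01 in shOC2 (SD, n = 2 each; log2 fold change -0.77, SE 0.09, edgeR adjusted p = 4.84e-05). REST, a repressor of neural genes, rose 1.44-fold, while FOXA1 fell 1.22-fold and HOXB13 fell 1.32-fold. UGT2B15 fell 6.54-fold and UGT2B17 9.67-fold, with the split of reads between them uncertain.

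Cell cycle genes fell in 28 of 32 cases and rose in 0 (camera adjusted p = 2.82e-12, adjusted p = 0.538 with an estimated correlation), with the replication helicase gene MCM3 2.79-fold and the mitotic regulator gene FOXM1 2.22-fold lower. STEAP4, which encodes a metalloreductase, rose 54.9-fold, EAF2 12.4-fold, TRPM8 4.38-fold and NDRG1 5.57-fold. The p53 targets rose in 12 of 18 and fell in 2 (14 and 2 adjusted over the list alone, adjusted p = 3.54e-05, adjusted p = 0.538 with an estimated correlation), ZMAT3 3.89-fold and the cell cycle inhibitor gene CDKN1A 2.57-fold. Hypoxia and glycolysis genes rose in 14 of 22 and fell in 3 (15 and 3 adjusted over the list alone, adjusted p = 0.0373, adjusted p = 0.759 with an estimated correlation).

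Replication-dependent histones rose in 12 of 13 and fell in 1 (camera adjusted p = 1.55e-18, adjusted p = 0.538 with an estimated correlation), with the linker histone gene H1-2 6.48-fold higher, and cytosolic ribosomal proteins rose in 21 of 35 and fell in 1 (adjusted p = 0.0373, adjusted p = 0.759 with an estimated correlation). Splicing and chromatin regulators fell in 11 of 19 and rose in 2 (adjusted p = 0.0140, adjusted p = 0.538 with an estimated correlation), with the neuronal splicing factor gene NOVA1 3.01-fold lower. Of 5 tested neuroendocrine markers 3 rose and 0 fell (adjusted p = 1.32e-05, adjusted p = 0.538 with an estimated correlation). SYT4, a synaptotagmin gene, was 25.8-fold higher at 203 ± 10.2 CPM. Only these 5 members of the list passed the filter, with a median log2 fold change of 0.88 and a mean of 1.47, so SYT4 weighs heavily in the result. The glucocorticoid list rose in 9 of 19 and fell in 3 (10 and 4 adjusted over the list alone, adjusted p = 0.0310, adjusted p = 0.538 with an estimated correlation), although NR3C1 itself was under 1 CPM in all 4 libraries.

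BCHE fell 33.6-fold and PEG10 10.1-fold, while DDC, which encodes dopa decarboxylase, rose 17.2-fold, UGT2B11 5.35-fold and UGT2B28 5.25-fold. VIM fell 7.27-fold. Among the steepest changes were the chemokine gene CCL28, at least 42.1-fold higher, the focal adhesion gene PARVA at 22.9 ± 2.15 CPM against 2 counts in all, the ephrin receptor gene EPHA3, 109.5-fold lower, and the guanylate cyclase subunit gene GUCY1B1, 61.0-fold lower. In all, 8969 of 16585 genes changed, 4525 higher and 4444 lower, and 2067 by at least 2-fold. Without shOC2 replicate 1 the count was 5076, and without shOC2 replicate 2 it was 5524.

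Genes that rose with overexpression in LNCaP fell with the hairpin in 1483 cases where independent lists would share 1270, and 1491 genes fell with the first and rose with the second against 1294. Calls in the same direction numbered 1252 higher and 1195 lower, against 1273 and 1290. Across the 15602 genes tested in both, the log2 fold changes had a Pearson correlation of -0.04. The overexpression calls here are those against control, and the overlap was not repeated with the calls against shCon. LAPC4 overexpression went the other way against the hairpin, with 1480 genes higher in both where independent lists would share 1309 and 1294 lower in both against 1164. Opposite calls numbered 1215 and 1140, against 1268 and 1202.

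Within the drug experiment, vehicle and combination were counted the same way, so this comparison comes first. It asked how 7 days of enzalutamide with the OC2 inhibitor differed from vehicle. ONECUT2 stood at 14.3 ± 1.43 CPM (SD, n = 3) against 15.9 ± 1.57 in vehicle (n = 3) and did not pass the test (log2 fold change -0.15, SE 0.15, edgeR adjusted p = 0.439). UGT2B17 rose 7.89-fold, UGT2B15 4.11-fold, HOXB13 1.47-fold, REST 1.31-fold and FOXA1 1.29-fold. NR3C1 stood at 0.76 ± 0.23 CPM against 0.42 ± 0.15 and did not pass the test.

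KLK3 fell 24.4-fold from 1660 ± 152 to 68.0 ± 9.17 CPM, KLK2 27.8-fold, HPGD 56.1-fold, SNAI2 32.6-fold and the co-chaperone gene FKBP5 8.28-fold. The opioid receptor gene OPRK1 was 123-fold, CCN3 26.4-fold and DDC 15.7-fold higher, and UGT2B11 was 6.35-fold and UGT2B28 18.7-fold lower. Glucuronidation genes split, with 6 of 8 lower and 2 higher (camera adjusted p = 0.0317, adjusted p = 0.402 with an estimated correlation).

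All 32 cell cycle genes fell (camera adjusted p = 2.37e-09, adjusted p = 0.379 with an estimated correlation), including E2F2 by 3.71-fold and the replication licensing gene CDC6 by 3.27-fold. Fatty acid synthesis genes fell in 10 of 13 (11 adjusted over the list alone, adjusted p = 1.02e-14, adjusted p = 0.0517 with an estimated correlation), ELOVL7 12.3-fold and ELOVL5 5.42-fold, both fatty acid elongases. Sterol synthesis genes fell in 18 of 21 and rose in 1 (19 and 1 adjusted over the list alone, adjusted p = 1.66e-07, adjusted p = 0.281 with an estimated correlation). Hypoxia and glycolysis genes fell in 14 of 22 and rose in 3 (15 and 3 adjusted over the list alone, adjusted p = 3.11e-05, adjusted p = 0.281 with an estimated correlation), hexokinase gene HK2 4.72-fold and lactate dehydrogenase gene LDHA 2.68-fold.

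The p53 targets fell in 12 of 18 and rose in 3 (13 and 4 adjusted over the list alone, camera adjusted p = 6.24e-05, adjusted p = 0.281 with an estimated correlation), led by the stress cytokine gene GDF15 at 5.13-fold and the death receptor gene FAS at 4.02-fold. The amino acid and ATF4 response fell in 15 of 20 and rose in 1 (adjusted p = 0.000336, adjusted p = 0.332 with an estimated correlation), and glucocorticoid targets fell in 11 of 20 and rose in 2 (12 and 2 adjusted over the list alone, adjusted p = 0.000134, adjusted p = 0.281 with an estimated correlation), the metallothionein gene MT1X 3.02-fold. Also lower were endoplasmic reticulum chaperones (12 of 18 lower, 1 higher, 13 and 1 adjusted over the list alone, adjusted p = 0.00840, adjusted p = 0.444 with an estimated correlation) and cytosolic ribosomal proteins (26 of 35 lower, 29 adjusted over the list alone, adjusted p = 3.62e-05, adjusted p = 0.488 with an estimated correlation). Mesenchymal genes fell in 6 of 12 and rose in 2 (7 and 2 adjusted over the list alone, adjusted p = 0.0368, adjusted p = 0.332 with an estimated correlation), and splicing and chromatin regulators fell in 11 of 19 and rose in 5 (12 and 6 adjusted over the list alone, adjusted p = 0.0180, adjusted p = 0.332 with an estimated correlation). Of the 13 mitochondrially encoded genes, 0 passed the test in edgeR.

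The steepest rises included DAB1, an adaptor gene of reelin signalling, at 27.3 ± 10.4 CPM against 2 counts in all, and the amine oxidase gene AOC1 (215-fold). The steepest falls were CCDC141, at 2 counts in all against 5.86 ± 0.23 CPM, the sperm maturation gene ADAM7 (158-fold) and the sialyltransferase gene ST6GALNAC1 (103-fold). In all, 8154 of 17439 genes changed, 4044 higher and 4110 lower, and 2561 by at least 2-fold.

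Enzalutamide was compared with vehicle across 2 counting steps. EEF1G, TOMM6 and 17 of the 18 protein-coding genes with a second annotated copy had 0 counts in every enzalutamide library. Of those 18, 14 were counted in vehicle and 13 in the combination, and vehicle held 133298 EEF1G counts in all. Absolute losses here therefore include genes the counting left out. All 10 of the steepest named falls were at 0 in every enzalutamide library, and each overlapped another gene or had a second copy. Of the genes named below in the comparisons with enzalutamide, TYMS, PLK1, PSMB8, IRF9, SLC7A5, HK2, MT1X, DDC, UGT2B11, TRPM8, FOXA1 and REST also share exons with another gene, so their folds may include the difference in counting. The same holds for UGT2B15 and UGT2B17, which share no exon with another gene but are near-identical in sequence. Between enzalutamide and vehicle libraries the correlation of log CPM lay between 0.656 and 0.689, and between combination and vehicle libraries between 0.898 and 0.918. Scaling by library totals gave 8546 genes higher and 4213 lower in place of 6053 and 6210 and moved the median of all genes from 0.01 to 0.35, so the balance of directions depended on the scaling.

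Within those limits, ONECUT2 stood at 26.1 ± 4.81 CPM under enzalutamide (SD, n = 3) against 15.9 ± 1.57 in vehicle, 1.64-fold higher (log2 fold change 0.71, SE 0.15, edgeR adjusted p = 0.00139). NR3C1 rose from 0.42 ± 0.15 to 6.81 ± 2.21 CPM, UGT2B17 2.31-fold and REST 1.34-fold. FOXA1 fell 1.38-fold (adjusted p = 0.000540), a call that ended with library totals (log2 fold change -0.12, adjusted p = 0.211). HOXB13 fell 1.17-fold (adjusted p = 0.0288), a call that turned to 0.11 with library totals and ended without vehicle replicates 1, 2 or 3 in turn (adjusted p = 0.0655, 0.0542 and 0.0537) or without the third enzalutamide column (0.103). UGT2B15 did not pass the test (log2 fold change -0.16, SE 0.19) but fell without the first enzalutamide column (-0.48, adjusted p = 0.000347).

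HPGD fell 112-fold, SNAI2 27.1-fold, KLK2 14.4-fold and the transcription factor gene MAF 14.1-fold. OPRK1 rose 161-fold and DDC 11.7-fold. Glucuronidation genes fell in 5 of 8 and rose in 1 (6 and 1 adjusted over the list alone, adjusted p = 0.0112, adjusted p = 0.798 with an estimated correlation), UGT2B28 90.8-fold and UGT2B11 37.7-fold. Fatty acid synthesis genes fell in 11 of 13 (adjusted p = 0.00254, adjusted p = 0.798 with an estimated correlation), with fatty acid synthase gene FASN 3.70-fold lower. Cell cycle genes were lower in 28 of 32, including TYMS by 11.4-fold and PLK1 by 4.67-fold, but the list did not pass the test (adjusted p = 0.0564).

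Interferon-stimulated genes rose in 16 of 23 and fell in 2 (camera adjusted p = 0.0429, adjusted p = 0.798 with an estimated correlation), with the immunoproteasome gene PSMB8 20.7-fold and the tetherin gene BST2 9.44-fold higher. The amino acid transporter gene SLC7A5 rose 11.8-fold. All 13 mitochondrially encoded genes (adjusted p = 0.000460, adjusted p = 0.798 with an estimated correlation) and 31 of 35 cytosolic ribosomal protein genes (34 adjusted over the list alone, adjusted p = 0.000644, adjusted p = 0.798 with an estimated correlation) fell, MT-ATP8, which overlaps MT-ATP6, by 113-fold. In all, 12263 of 17439 genes were called, 6053 higher and 6210 lower, and 6330 by at least 2-fold.

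The last comparison, combination vs enzalutamide, asked what adding the OC2 inhibitor changed, and it crosses the same counting steps. ONECUT2 was 1.82-fold lower in the combination (log2 fold change -0.86, SE 0.15, edgeR adjusted p = 0.000528) and NR3C1 8.93-fold lower, at 0.76 ± 0.23 against 6.81 ± 2.21 CPM (n = 3 each). FOXA1 was 1.78-fold, HOXB13 1.72-fold, UGT2B15 4.61-fold and UGT2B17 3.42-fold higher. REST did not pass the test (-0.03, SE 0.09), but was lower with library totals (-0.29, adjusted p = 0.0181).

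KLK3 was 4.35-fold, TRPM8 3.48-fold and NDRG1 2.67-fold lower. Glucuronidation genes were higher in 6 of 8 and lower in 1 (adjusted p = 0.0621), UGT2B11 5.95-fold and UGT2B28 4.86-fold. Hypoxia and glycolysis genes were lower in 14 of 22 and higher in 1 (adjusted p = 0.000778, adjusted p = 0.744 with an estimated correlation), HK2 4.81-fold. The amino acid and ATF4 response was lower in 16 of 20 and higher in 2 (adjusted p = 0.0419, adjusted p = 0.744 with an estimated correlation), SLC7A5 21.7-fold. Interferon-stimulated genes were lower in 17 of 23 and higher in 3 (18 and 3 adjusted over the list alone, adjusted p = 0.00796, adjusted p = 0.744 with an estimated correlation), PSMB8 18.1-fold, while IRF9 was 14.3-fold higher. The p53 targets were lower in 14 of 18 and higher in 2 (adjusted p = 0.0258, adjusted p = 0.744 with an estimated correlation), and all 13 mitochondrially encoded genes were higher (adjusted p = 0.000443, adjusted p = 0.744 with an estimated correlation). EEF1G, at 1606 ± 112 CPM in the combination and 0 under enzalutamide, and MT1X, 48.6-fold higher, differ between columns counted differently. In all, 10790 of 17439 genes were called, 5484 higher and 5306 lower, and scaling by library totals gave 3899 higher and 7848 lower.

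Of the genes called for enzalutamide vs vehicle, 8086 were called the other way for combination vs enzalutamide (3816 and 4270 by direction), where independent lists would share 1842 and 1953. Simulated groups without any effect gave 0 in 20 draws, which does not measure how many opposite calls the shared libraries add where effects are present. Both contrasts share the enzalutamide libraries with opposite sign, so part of the excess may come from them and from their counting. Of these genes, 5117 were not called for combination vs vehicle. Enzalutamide and combination moved 2617 genes up and 2734 down together against vehicle. Both contrasts share the vehicle libraries, so the 1404 and 1464 that independent lists would share are not what to expect without a common effect. The simulated groups gave 0 here too, with the same limit, so how much of this overlap the shared libraries add is not known.

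Genes higher with OC2 overexpression than in control in LNCaP were lower in combination vs enzalutamide in 1177 cases. This is fewer than the 1333 that independent lists would share. Genes lower with OC2 overexpression than in control were also lower in combination vs enzalutamide in 1496 cases, against 1210. The LNCaP overexpression lists rest on control as the reference, and their overlaps were not repeated against shCon. Against vehicle, 1320 of the genes higher with overexpression in LNCaP were lower with the combination, where 1227 would be shared. For LAPC4, 1248 raised genes were lower with the combination against 1256, and 1219 were higher in both against 1096. The hairpin and the combination moved genes together more often than independent lists, with 1216 higher in both against 1002 and 1386 lower in both against 1091. The correlation across the 13891 genes was, however, -0.01 (Pearson) and 0.08 (Spearman). The combination also holds enzalutamide, and no arm received the inhibitor alone. The overlaps with combination vs vehicle therefore cannot be assigned to the inhibitor.

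**Figure D4:**
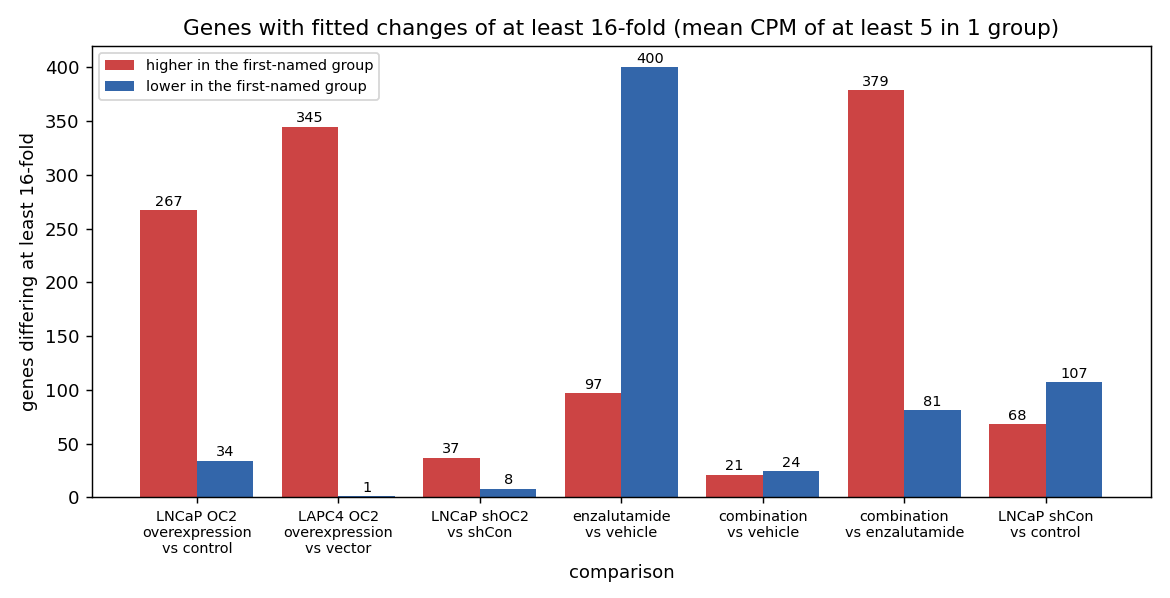
Number of genes with a fitted change of at least 16-fold and a mean of at least 5 CPM in the higher group (vertical axis) per comparison (horizontal axis), higher in red and lower in blue in the group named first. LAPC4 overexpression has 345 rises and 1 fall, and LNCaP shCon and control differ in 68 and 107.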

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

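The effect of OC2 overexpression differed between LAPC4 and LNCaP in the interaction test for 9713 genes (edgeR, adjusted p under 0.05). ONECUT2 itself rose further in LAPC4, by a difference of log2 fold changes of 2.34, so the rise in OC2 was not the same in the lines. Among the fixed genes, the difference of log2 fold changes, LAPC4 minus LNCaP, was -1.26 for FOXA1, -3.12 for NR3C1 and -5.45 for UGT2B15. Medium, with R1881 named for LAPC4 only, cannot be told apart from line in these differences. Their sizes also depend on the LNCaP control libraries. With shCon as reference, the LNCaP log2 fold changes were -0.20, 4.66 and 1.54, in place of 0.24, 6.01 and 5.27. The largest positive differences were TGM2 (15.50), HEXA (13.28), KIRREL1 (12.95), ZDHHC4 (12.40) and GALNT14 (12.04), and the largest negative ones TUNAR (-14.99), SSX2 (-13.32), DOK6 (-13.25), EPHA7 (-12.39) and SLC6A10P (-12.02). TGM2 went from 3.33 to 0.14 CPM in LNCaP and from 0.32 to 639 CPM in LAPC4. HEXA and ZDHHC4 had 0 counts in LAPC4 vector, and the 5 negative ones 0 counts in LNCaP control, so their fitted differences are no bounds. FOXA1, TGM2, HEXA, ZDHHC4, GALNT14, DOK6 and SLC6A10P share exons with another gene.

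In what follows, the tests of genes at 0 under enzalutamide, of cells of another line, and of another counting step in LAPC4 were chosen only after the result was seen. The other predictions were written before their values were computed.

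The first pattern is that the enzalutamide libraries stand apart from vehicle and combination. Among protein-coding genes at 0 in every enzalutamide library and well counted in vehicle, 93.6% overlap another gene or have a second copy, against 49.4% of all tested ones, which fits another counting step. Without genes that overlap or are missing from an arm, 67.1% were still called, against 70.3% of all genes, so overlap alone is excluded as the whole cause. GC content (Spearman rho -0.15) and transcript length (0.20) leave their share open. Of genes within 0.25 log2 units between combination and vehicle, 66.0% were called for enzalutamide, so a drug effect that the inhibitor undoes cannot be told apart from a separate culture or library batch.

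The second pattern is the transcripts new to LAPC4 with OC2, with 345 rises and 1 fall of at least 16-fold. Cells of another line in the overexpression cultures would bring rises without falls, but that asymmetry is the pattern itself and no other value decides, so such cells cannot be told apart from an action of OC2 on silent genes. LNCaP cells are argued against as the whole cause. Of the 198 rising genes that could be compared, 160 (80.8%) stood in every overexpression library above every LNCaP library of the overexpression and hairpin experiments. Added LNCaP cells could not bring them so high, although the levels compared come from tables that were counted differently. Of 10 genes of LNCaP that LAPC4 vector lacks, 8 stood under 0.01 of their LNCaP level in the overexpression libraries, 3 of them with no count anywhere in this table, while ME1 (0.29) and C9orf64 (0.69), singled out after their values were seen, stood higher. Overlap with other genes does not account for the pattern as a whole, since 26.9% of the protein-coding genes new to these libraries (7 of 26) overlap others. Among all tested ones the share is 48.9%. Other differences in counting were not tested. Genotypes in the reads could separate cells of another line from an action of OC2.

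The third pattern is the transcripts new to LNCaP with OC2, with 267 rises and 34 falls of at least 16-fold. Cells of another line beside resident control cells could not bring those 34 falls. The falls are measured against control alone, and 107 genes were also at least 16-fold lower in shCon than in control. A difference of stocks could bring such falls, so they do not exclude added cells as a source of the rises. LAPC4 cells are argued against as the whole cause of the rises. Of the 159 rising genes that could be compared, 112 (70.4%) stood in every overexpression library above every LAPC4 library. The levels compared come from tables that were counted differently. The 25 genes of LAPC4 that LNCaP control lacks spread widely, at a median 0.0175 of the LAPC4 level (quartiles 9.7e-04 and 0.105), with 10 under 0.01 and 7 at 0.1 or more, so they leave LAPC4 cells as a source of part of the rises open. Separate LNCaP stocks fit, since 175 genes differed at least 16-fold between shCon and control, neither of which carries an OC2 construct per the labels, beside 301 between overexpression and control. Part of the LNCaP overexpression result may therefore reflect a difference of stocks, and an effect of OC2 was not separated from it.

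Each comparison of 3 with 3 libraries allows 10 splits, which cannot reach 0.05. Fitted as 2 arms with edgeR, only 1 split, the real one, gave as many calls in LAPC4 overexpression (10329), enzalutamide vs vehicle (11734), combination vs vehicle (9393) and combination vs enzalutamide (9862), and the highest other count was 0. At unadjusted p under 0.05 the real splits gave 10965, 12258, 10095 and 10747 genes, and the highest others 433, 253, 228 and 518.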

How the results depend on the processing

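Requiring an absolute log2 fold change of at least 1 lowered the counts by construction, to 4233 for LNCaP overexpression, 3548 for LAPC4 overexpression, 2067 for shOC2, 6330 for enzalutamide vs vehicle, 2561 for combination vs vehicle, 5001 for combination vs enzalutamide, 632 shared between the lines (from 3066), 3909 called for enzalutamide vs vehicle and the other way for combination vs enzalutamide (from 8086) and 308 higher with OC2 and lower in combination vs enzalutamide (from 1177). With only genes without exonic overlap and counted in every arm, chosen after seeing the data, fewer genes were tested and the drug counts were 5024, 3883 and 4153 of 7491. Leaving out 1 library, where a lone library is assumed to vary like the others, gave 8432 to 9227, 8856 to 12089, 5076 to 7863 (shOC2), 11391 to 13040, 6579 to 9880 and 9736 to 12258 in the order above, 8472 to 10777 for the difference between lines, 2470 to 3430 shared, 7387 to 8962 called the other way and 939 to 1265 higher and lower. All other settings kept these counts within 1.5 times. The highest drug counts with 1 library left out were 13040, 9880 and 12258, and all were those without the first enzalutamide column. Directions turned, with the cause not tested, for HOXB13 in LNCaP overexpression (-0.0690 to 0.0502 without 1 library), REST in LAPC4 (-0.11 to 0.0179), in combination vs enzalutamide (-0.103 to 0.0472) and between lines (-0.0284 to 0.124), none of them called. With library totals HOXB13 (0.11) and UGT2B15 (0.18) turned for enzalutamide vs vehicle. The share of calls that were higher went from 49.4% to 67.0% for enzalutamide vs vehicle and from 50.8% to 33.2% for combination vs enzalutamide, where the median of all genes moved to -0.28. It went from 50.5% to 43.7% for shOC2 and from 49.6% to 58.5% for combination vs vehicle. With the replicate number as a block, counts were 11256 for LNCaP overexpression, 9808 for LAPC4, 8521 for shOC2 and 9375 for combination vs vehicle. The last was fitted on its 2 arms alone, which gave 9393 without a block. The labels do not say that the numbers pair samples. Same-numbered libraries deviated with correlations of 0.279 in LNCaP overexpression and 0.0271 in shOC2, with 2 pairs each, and 0.0883, -0.108 and -0.151 in LAPC4. For combination vs vehicle (0.231, 0.202 and 0.0915), every sample correlated best with its own number, a hint from the data only. Under the block, ribosomal proteins in shOC2 (adjusted p = 0.0507) and glucuronidation (0.436) and mesenchymal genes (0.199) in combination vs vehicle were not called. For combination vs vehicle, leaving out the enzalutamide arm may also be the reason, since lists were not tested on the 2 arms without a block. No paired analysis was possible for enzalutamide because its columns carry no matching replicate number. Of 50 list calls reported here, all held with DESeq2 size factors, fry did not call hypoxia (0.193) and ribosomal proteins (0.0735) in shOC2, and an estimated correlation kept 1, mesenchymal genes in LAPC4.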

Other observations

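Among Wnt pathway genes no comparison passed camera, with 9 of 17 higher and 1 lower in LNCaP overexpression (10 and 1 adjusted over the list alone, adjusted p = 0.0672), 2 higher and 7 lower of 13 in shOC2, and 6 higher and 2 lower of 15 with the combination. The transcription factor gene LEF1 fell 6.81-fold in shOC2 and rose 4.98-fold with the combination (20.9 ± 8.32 against 4.19 ± 1.18 CPM, n = 3), and the ligand gene WNT5A fell 5.04-fold in shOC2. CCND1, which encodes cyclin D1, rose 3.60-fold with overexpression in LNCaP, and MYC fell 2.72-fold with the combination. Hepatic and intestinal lineage genes rose in 3 of 4 in LAPC4 (4 adjusted over the list alone, camera adjusted p = 0.00820, adjusted p = 0.257 with an estimated correlation). Most members of this list did not pass the filter, and 1 of the 4 was at 0 in vector and could enter only as a rise.

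Steroid synthesis and conversion genes rose in 7 of 11 and fell in 1 in LNCaP overexpression (camera adjusted p = 0.728), where the sulfatase gene STS fell 3.20-fold (log2 fold change -1.68, and -0.49 against shCon). Against shCon this list went 2 higher and 7 lower of 11, so its direction turned with the reference. It went 5 higher and 6 lower of 12 in shOC2. Of the growth factor receptors, EGFR fell from 101.5 ± 4.47 to 25.4 ± 0.49 CPM (from 55.1 to 26.8 CPM against shCon, log2 fold change -1.04) and IGF1R rose 3.08-fold in LNCaP overexpression. Against shCon, IGF1R turned and was not called (log2 fold change -0.17, adjusted p = 0.159). IGF1R fell 6.93-fold with the combination.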
